A study of Drosophila melanogaster with 4 samples.

How the data were processed

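Total RNA from pooled adult Drosophila melanogaster was measured on microarray slides with 2 dyes, per the labels. The 4 samples are 2 pools of females and 2 pools of males of a single genotype, each labelled with Cy3 or Cy5, and the series' design calls the replicates independent. Per the labels, 1 female and 1 male pool were handled without a wash and 1 of each with a wash, and the 2 sexes were set against each other on 2 slides with the dyes exchanged. The labels do not number the slides. In the scanner files the spot flags agreed at every spot between the 2 samples without wash and between the 2 samples with wash, and differed between these pairs, so each wash state was taken as 1 slide. What the wash was, how many flies a pool held, the array's maker, the scanner and the image software are not given in the sources used here.

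The authors' deposited scanner files give, for each of 22575 spots in 105 rows and 215 columns, the mean, median and mode pixel intensity of the spot and of its local background, in 1 dye channel per file, with no background subtracted. The authors' deposited value table holds the natural log of mean signal minus mean background of the same spot. This was found by setting both side by side: no value differed by more than 1e-07, and entries are blank where the signal did not exceed the background. No scaling between channels had been applied to it. Its medians were 3.94 for females and 3.92 for males without wash, and 4.09 for females and 4.48 for males with wash. The gene name field is blank at every spot, so spots are named here by their number, counted along the rows, with their row and column. The gene lists, the comparison of X-linked with autosomal genes and the averaging of probes by gene that were fixed before the data were examined were not analysed here, and control spots could not be marked as such.

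Spots flagged on either slide (647, leaving 21928) were given no weight and were not tested. Mean pixel intensities were background-corrected with normexp and an offset of 50, the Cy5/Cy3 log ratio was normalized within each slide by loess, and mean intensities were matched between slides by Aquantile normalization. Log2 values per channel were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with sex and slide as terms, and p-values were two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. This left 1 residual degree of freedom per spot, and 2.86 after the prior from all spots was added. Because the dyes were exchanged, a dye effect cancels in the mean female minus male difference, while any dye effect of a single spot enters its residual. The same contrast is also the difference in sex effect between wash states, which therefore cannot be told apart from dye. Each wash state is 1 slide, so wash and slide cannot be told apart, and a test of the slide term compares these 2 slides and not the wash conditions. The Cy3 minus Cy5 difference was tested in a fit with sex and dye, added after seeing the data. An exact test of 2 samples against 2 cannot go below p = 0.333, so every p-value rests on the spread pooled over spots. In the main fit the p-values measure how far the female/male ratios of the 2 slides disagree, and these slides also differ in dye and wash. A difference between the slides that both sexes share is taken up by the slide term and does not enter them.

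The offset makes fold changes of dim spots too small. The procedure was tested on simulated data over 21928 spots, with the noise SD of a spot capped at 0.5 (log2), since uncapped noise broke the background step. With 6000 spots changed in the female against male comparison, the whole procedure called 59.2% of spots simulated at 2-fold, 86.8% at 4-fold and 92.4% at 8-fold, and 3.95% of its calls were unchanged spots. The median measured log2 difference of the 8-fold spots was 1.59 in place of 3. With 200 changed spots the whole procedure called 0, while the fit alone called 59 of 67 spots at 4-fold. Both simulated channels of a slide started from the same signal at each spot. Spots far brighter in Cy3 than in Cy5, which the data hold, were therefore absent, and these shares need not carry over to the data.

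A spot was counted as above background where its mean signal was at least 2 times its mean background, since no pixel spread or negative control is marked. Local background was called raised above 1.25 times the channel's median. The spots to be named were chosen by a rule fixed before the data were examined: the 15 largest differences in each direction past the threshold, in the same direction on both slides and above background in both samples of the higher sex, and for the slide difference the 5 largest in each direction moving the same way in both sexes. With no gene names, the first 2 of each are given. Alternatives covered background correction, normalization, filters on dim spots, the slide block, the prior, the deposited value table and each sample left out. The bounds of the corner, of raised background, of the outer columns and of Cy3-bright spots, the use of median pixels, the removal of Cy3-bright spots or of 1 corner of a slide, and the keeping of flagged spots were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9. The number of slides limits the precision.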

Results

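RNA of 2 pools of adult female and 2 pools of adult male fruit flies was compared on 2 slides of 22575 spots, 1 slide without and 1 with a wash, with the dyes exchanged between them. The female pool was labelled with Cy5 and the male pool with Cy3 on the slide without wash, and the other way round on the slide with wash. The median signal over local background was 2.22 in the female and 3.11 in the male channel without wash, and 3.47 in the female and 3.21 in the male channel with wash. A median pixel of 65000 or more was found at 3 female and 2 male spots without wash, and at 0 female and 4 male spots with wash. Samples resembled each other by sex more than by slide or dye. Across the 21928 unflagged spots, which are not independent replicates, the log2 background-subtracted signals of the 2 female samples correlated with r = 0.87 and those of the 2 male samples with r = 0.86, while the 4 pairs of opposite sex had r between 0.72 and 0.75.

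The first comparison asked which transcripts differ between intact females and males. Many spots differed between the sexes: 7322 of 21928 spots (33.4%) passed the threshold, 4016 higher in females and 3306 higher in males (limma, Benjamini-Hochberg adjusted p under 0.05). The median log2 difference, female minus male, was 1.15 among the female-higher and -0.88 among the male-higher spots. Larger differences were mostly in the female direction. Over 2-fold in the same direction on both slides were 2114 spots higher in females and 1136 higher in males. Over 4-fold these numbers were 948 and 159, all of which also passed the limma threshold, and over 8-fold they were 428 and 29. The female excess over 4-fold held under the 4 other scalings run, where the counts were 797 against 227 with quantile normalization, 710 against 247 with median scaling, 459 against 198 with none and 825 against 548 in the authors' value table. The value table also differs in background correction, with plain subtraction and no offset. On the slide without wash alone the counts were 1046 against 644, and on the slide with wash alone 1490 against 189. Spots far brighter in Cy3 than in Cy5, described with the wash comparison, enter such single-slide counts: they made up 422 of the 644 and 423 of the 1490, and left out they leave 1046 against 222 and 1067 against 189. The balance of all calls did not hold: females had the higher value in 54.8% of calls after loess, but in 44.7% after quantile normalization, 42.4% after median scaling only, 38.1% in the authors' value table as deposited and 92% of the 50 calls with no normalization. The median female minus male difference over all tested spots was 0.01 (log2) after loess, -0.03 after quantile normalization and 0.00099 after median scaling, but -0.19 with no normalization and -0.35 in the authors' value table, so counts under the last 2 are relative to a shift towards males.

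**Figure D1:**
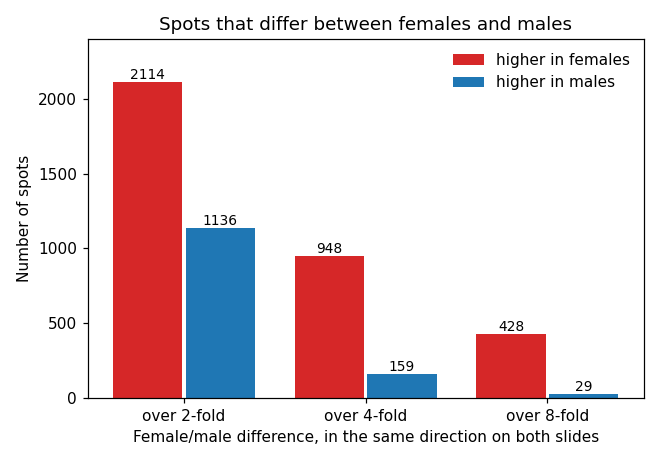
Number of spots (vertical axis) whose female/male difference exceeded 2-fold, 4-fold or 8-fold in the same direction on both slides, after loess, for spots higher in females (red) and higher in males (blue). Females had 948 against 159 spots over 4-fold and 428 against 29 over 8-fold.

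The largest female-higher differences were far larger than the spread between the 2 samples of a sex. Spot 6866 (row 32, column 201) had a log2 signal of 13.45 ± 0.00063 in females and 6.47 ± 0.23 in males (SD, n = 2 each), a difference of 6.97 (SE 0.13, limma adjusted p = 0.0057), or 126-fold. Its log2 ratio was 6.81 on the slide without wash and 7.14 on the slide with wash. Spot 13606 (row 64, column 61) had 13.32 ± 0.14 in females and 6.70 ± 0.054 in males (SD, n = 2 each), a difference of 6.62 (SE 0.090, limma adjusted p = 0.0057), or 98.6-fold. Their sizes depended on the processing: over 20 alternatives the log2 difference of spot 6866 was 6.45 to 7.84 and that of spot 13606 was 6.11 to 7.36, each highest with plain background subtraction. The 15 largest female-higher spots reached from 126-fold down to 48.4-fold.

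The largest male-higher differences were smaller. Spot 12653 (row 59, column 183) had a log2 signal of 7.74 ± 0.16 in females and 12.67 ± 0.025 in males (SD, n = 2 each), a female minus male difference of -4.93 (SE 0.099, limma adjusted p = 0.0057), or 30.5-fold. Its log2 ratio was -4.84 without wash and -5.02 with wash. Spot 7868 (row 37, column 128) had 8.26 ± 0.42 in females and 12.68 ± 0.073 in males (SD, n = 2 each), a difference of -4.42 (SE 0.17, limma adjusted p = 0.0062), or 21.4-fold. Over the 20 alternatives the difference was -5.79 to -4.82 for spot 12653 and -5.14 to -4.12 for spot 7868, each largest in the authors' value table. The 15 largest male-higher spots reached from 30.5-fold down to 10.6-fold. All 4 samples were above 2 times background at each of these 4 spots. Genes cannot be named, since the gene name field used here is blank.

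Bright spots gave most of the calls in both directions. Of the female-higher spots, 2375 lay among the brightest 7309 tested spots by mean log2 signal, 1317 among the next 7309 and 324 among the dimmest 7310. Of the male-higher spots, 2102, 922 and 282 lay in these sets. Each call rests on 2 samples per sex, which also differ in dye and wash. The count was 4683 without the slide term, 3432 in the authors' value table and 50 with no normalization (limma, same threshold). Leaving out each sample in turn also meant leaving out the slide term, and gave 2783 to 4161, against the 4683 without that term.

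The second comparison concerned the wash, the subject named in the study's title. Local background was uneven on the slide without wash and nearly flat on the slide with wash. Its SD over spots was 19.1 in the female and 20.8 in the male channel without wash, against 1.03 in the female and 2.97 in the male channel with wash. Extreme spots enlarge these SDs: the highest background was 2323 (female) and 2941 (male) without wash, against 54.5 and 174 with wash. The median background followed the dye and not the wash, at 41.2 (Cy5, without), 23.1 (Cy3, without), 24.2 (Cy3, with) and 39.9 (Cy5, with) intensity units. Raised background was found at 741 female (3.28%, 95% exact binomial interval 3.05 to 3.52) and 846 male spots (3.75%, 3.50 to 4.0035) without wash. With wash it was found at 44 female (0.195%, 0.142 to 0.262) and 98 male spots (0.434%, 0.353 to 0.529). The intervals cover counting error only, since neighbouring spots are not independent. The scanner files flagged 474 spots on the slide without wash and 181 on the slide with wash, 8 of them on both.

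**Figure D2:**
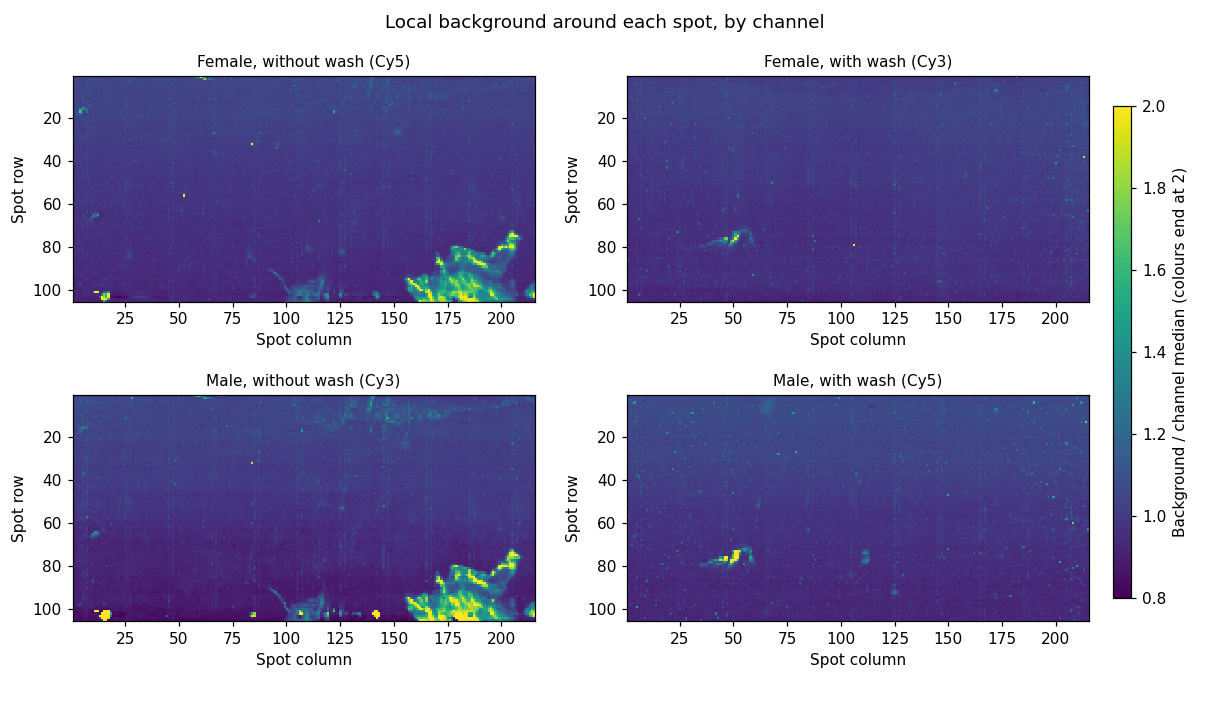
Local mean background around each spot, divided by the channel's median, at the spot's row (vertical axis) and column (horizontal axis) for the 4 samples; colours end at 2. Without wash, both channels share a raised area in the lower right corner, which held 649 of the 741 raised female spots and 695 of the 846 raised male spots.

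Most of the raised background lay in 1 corner of the slide without wash (the last 26 rows and last 61 columns, 1586 spots). The corner held 649 of the 741 raised female spots and 695 of the 846 raised male spots, against 0 and 3 on the slide with wash. Median spot signal without wash, with no background subtracted, was 156 in the corner and 88.4 elsewhere in the female channel, and 110 against 70.1 in the male channel. With wash it was 91.8 against 83.4 in the female and 150.3 against 127 in the male channel. Of the 474 flagged spots without wash, 306 lay in this corner. Without the corner, 6980 of 20656 tested spots passed the threshold for sex, against 7322 of 21928 with it.

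The share of spots at or above 2 times background was higher with wash for each dye. In Cy5 it was 55.3% without wash (female) and 73.9% with wash (male), and in Cy3 86.3% without wash (male) and 91.8% with wash (female). These pairs differ in sex as well as in slide. With 1 slide per wash state these values have no replicate check, and wash cannot be told apart from slide.

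The female/male ratio was set side by side on the 2 slides. Over all 21928 spots the log2 ratios correlated with r = 0.55 (Spearman's rho = 0.76), across spots that are not independent replicates, with SDs of 1.06 without and 1.07 with wash. A separate cloud of spots ran against the rest: 449 spots had ratios over 2-fold in opposite directions, all 449 lower in females without wash and higher in females with wash, which is the direction of a higher Cy3 signal. Of the array's spots, 433 were at least 8-fold brighter in background-subtracted signal in the Cy3 than in the Cy5 channels on average, and 426 of these were tested. These spots were selected on the Cy3 over Cy5 excess, which is also the difference between the ratios of the 2 slides, so leaving them out raises r by construction. Without them r was 0.94 over 21502 spots, with a slope of 0.93 and SDs of 0.97 without and 0.95 with wash. With them left out before normalization, which changes both the normalization and the pooled spread, 8792 spots passed the threshold for sex, including all 7322.

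**Figure D3:**
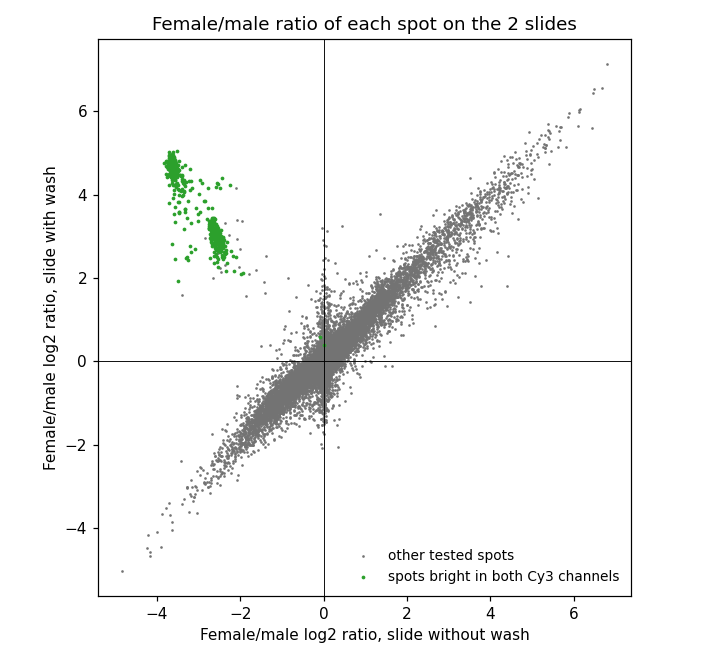
Female/male log2 ratio of each of 21928 tested spots on the slide without wash (horizontal axis) and with wash (vertical axis), after loess. Spots at least 8-fold brighter in both Cy3 channels on average are green. They were selected on the difference between the 2 ratios, which is their distance from the diagonal (r = 0.55 with and 0.94 without them). Over the whole array, the 8-fold bound was passed by 433 spots in the Cy3 direction and 2 in the Cy5 direction.

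After normalization, the difference between the slides themselves was smaller than that between the sexes. Aquantile normalization matches mean intensities between slides, so the 2 differences are not on an equal footing. The slide differences of females and males correlated with r = -0.29 across spots, and opposite movements cancel in their mean. With the dyes exchanged, a Cy3 excess raises the female and lowers the male slide difference, so dye pulls this r down. The SD of Cy3 minus Cy5 was 0.50 (log2) over all tested spots. Without the Cy3-bright spots, selected on that contrast, it was 0.17, against 0.38 for the slide difference. This r therefore does not show that females and males changed differently between slides. The SD of the mean slide difference over spots was 0.37 (log2), against 0.94 for female minus male. Over 2-fold between slides in both sexes were 375 spots. Of these, 361 were higher and 14 lower with wash, and all 14 lay in the corner with raised background. Spot 919 (row 5, column 59) was higher with wash by 3.71 in females and 3.33 in males (log2), and spot 19314 (row 90, column 179) by 2.92 and 2.62. Lower with wash were spot 22108 (row 103, column 178), at -2.12 in females and -2.21 in males, and spot 22115 (row 103, column 185), at -1.86 and -1.44. In limma 0 spots passed the adjusted threshold for the slide term, and 7862 had an unadjusted p under 0.05. Without the Cy3-bright spots 4523 passed it. When the median pixel replaced the mean pixel, 6 of the 361 spots stayed over 2-fold higher with wash in both sexes.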

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

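All tests in this part were chosen after the result was seen. The 449 spots with ratios over 2-fold in opposite directions on the 2 slides stand out because they share 1 direction. All 449 were lower in females without wash and higher in females with wash, and 0 went the other way round. With sex and dye in the fit, limma called all 449 for the Cy3 minus Cy5 difference (highest adjusted p 0.0122), as part of 468 called among all tested spots, 460 of these higher in Cy3. The 449 were selected on the size of this difference, and the test cannot say whether it comes from dye or from a sex difference that depends on the wash. Of the 449, 424 are among the Cy3-bright spots, whose median Cy3 over Cy5 excess was 4.35 (log2). Their median log2 background-subtracted signal was 9.23 in males without wash and 9.41 in females with wash (both Cy3), against 3.96 in females without wash and 5.25 in males with wash (both Cy5), and the 2 Cy3 channels correlated with r = 0.98 across these spots. Only 2 spots had an 8-fold excess of Cy5.

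By the design, such spots could follow the dye or a sex difference that depends on the wash, and intensities alone cannot separate these. Of the 433 spots, 52.0% had another 7 columns away in the same row, against at most 9.70% in 10000 random placements. Other rows held a different spacing, as in row 23 at columns 1, 9 and 17, and this share does not count it. Of the 433, 90% lay in 12 rows of the array, while as many spots drawn at random from those called for sex never filled fewer than 73 rows. This argues against many different genes with a wash-dependent sex difference, and is consistent with array features placed at regular positions, such as control features that take up Cy3. Which features they are stays open, as no control annotation was used here.

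Flags and local background were not themselves compared between the sexes, though both enter the processing of the signals. The slide without wash had 474 flagged spots, against 181 with wash. Raised background was found at 741 spots of its female channel and 846 of its male channel, against 44 and 98 on the slide with wash. In the corner that held most of these, the log2 spot signal exceeded the rest of the slide by 0.54 more than on the slide with wash, where 11 other windows of the same size ranged from -0.35 to 0.17. No background was subtracted here, so the raised local background is part of this excess. Without the Cy3-bright spots, the SD of the log2 female/male ratio in the corner was 0.936 times that on the slide with wash, against 0.975 to 1.06 in the other windows.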

How the results depend on the processing

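No call shared between the main fit and any of the 20 alternatives changed direction, and the 4 named spots passed the threshold in all 20, with the sizes given beside them. The number of spots past the threshold for sex was 7322. It was 50 with no normalization (46 higher in females, 4 in males; 1544 at an unadjusted p under 0.05) and 3432 in the authors' value table (1306 and 2126), with 2433 of these shared with the main calls. Without the slide block, which is the pairing of the samples (no replicate block), it was 4683, with 2000 higher in males, and with dye in place of the slide 4646, with 1912 higher in males. Each sample was also left out in turn, without the block and with the lone sample of a sex assumed to vary like the others. This gave 3334 spots (2068 higher in females, 1266 in males) without female replicate 1, 4161 (2402 and 1759) without female replicate 2, 3205 (2124 and 1081) without male replicate 1 and 2783 (1783 and 1000) without male replicate 2. With median pixels, 5010 spots were higher in males, and 10207 passed in all, with 7285 shared with the main calls. The other 11 alternatives gave 6557 to 8835. Over 4-fold, male-higher spots numbered 159, but 270 with plain background subtraction, 247 with median scaling, 548 in the value table, 644 on the slide without wash alone and 189 on the slide with wash alone. Female-higher spots numbered 948, but 459 with no normalization, 1046 on the slide without wash alone and 1490 on the slide with wash alone. The correlation of ratios between slides was 0.554 with a slope of 0.563. Both were 0.535 and 0.546 with median scaling only and with no normalization, 0.939 and 0.931 with the Cy3-bright spots, selected on the disagreement between slides, left out before normalization, and 0.576 and 0.598 with median pixels, and the slope was 0.546 in the upper 50% by intensity. The slide term had 0 calls, but 2620 with median scaling only and 4523 without the Cy3-bright spots. Raised background, averaged over channels, was 3.51% of spots without wash (2.81% with median pixels, 2.02% with flagged spots left out) and 0.315% with wash (0.0687% and 0.173%). Beyond the smaller sets of spots and samples that some alternatives use, the cause was not tested. A random slide block was not run because the correlation within slides gave no estimate at any spot. Fits per probe and with the median of probes, the gene lists and the X-linked comparison were not run for want of gene names. Fewer calls lay among the dimmest 7310 spots (324 higher in females, 282 in males) than among the brightest 7309 (2375 and 2102).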

Other observations

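The 4-fold counts with plain background subtraction, under the other scalings and on 1 slide alone used settings fixed before the data were examined. Their use to weigh explanations, and the other tests whose values are weighed in this part, were chosen after the results were seen. Technical explanations were weighed for the female excess over 4-fold, with the biological one, the sex of the flies, untested for want of gene names. If male-higher spots were dimmer and so more compressed by background and offset, plain background subtraction with no offset should bring the counts near each other. After loess they were 1395 against 270, a ratio of 5.17 (95% exact binomial interval 4.53 to 5.91, for counting error only). With normexp and the offset this ratio was 5.96. Without loess the counts came nearer to each other. The ratio was 2.32 with normexp, the offset and no normalization. It was 1.51 (1.35 to 1.68) in the authors' value table, which has neither normexp nor an offset. Compression therefore stays open for part of the female excess. Of the 3306 male-higher calls, 2102 lay among the brightest 7309 tested spots, as did 2375 of the 4016 female-higher calls. The brightness of calls cannot weigh this explanation, since compressed dim spots would also tend to miss the threshold. The scaling of the channels also stays open for part of the female excess. With normexp and the offset, the ratio was 5.96 after loess, 3.51 after quantile normalization, 2.87 after median scaling and 2.32 with none. The median difference over all spots was 0.0063 after loess and 0.00099 after median scaling (log2), so it does not account for the fall between these 2. In the value table, at 1.51, the background correction differed as well, and the median of all spots was shifted by -0.35 (log2) towards males. On the slide without wash alone the counts were 1046 against 644, with 422 Cy3-bright spots among the 644.

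A test planned before its result was seen, on spots whose brighter sex lay in the top 20% of signal, decides nothing, since a large difference itself brings a spot into that set. The set held 852 of the 948 female-higher and 158 of the 159 male-higher spots over 4-fold, and the share over 4-fold in it was 4.59 times as large for female-higher spots.

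The 361 spots over 2-fold higher with wash in both sexes had uneven pixels. The log2 ratio of their mean to their median pixel had a median of 1.44 on the slide with wash and -0.0045 on the slide without wash, and was 0.056 over all tested spots with wash. With median pixels, 6 of the 361 stayed over 2-fold (1.66%), while 99.1% of the 3250 spots over 2-fold for sex did. This argues against transcripts more abundant in the samples of that slide, and is consistent with a few bright pixels inside these spots, such as specks left on the slide. Of the 361, 54.0% lay in the outer columns (the outer 31 on each side), which held 28.5% of tested spots. For sex, 14 of the 361 were called, against 7322 of all 21928 tested spots (33.4%). The 361 were selected on a rise in both channels of 1 slide. Such a rise can move that slide's female/male ratio away from the other's, so the low share decides nothing.

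Over all tested spots, the SD of the 3 contrasts of the design was 0.94 for female minus male, 0.37 for with minus without wash and 0.50 for Cy3 minus Cy5 (log2), and 3723, 629 and 473 spots exceeded 2-fold in these contrasts. Without the Cy3-bright spots, which were selected on the last contrast, the SDs were 0.95, 0.38 and 0.17, and the counts 3723, 624 and 49.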
